A study of Mus musculus with 2 samples.

How the data were processed

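Single-cell RNA libraries of sorted MHC class II and CD11c-positive mononuclear cells from the central nervous system of mice with EAE were analysed, 1 from WT mice and 1 from Stat4fl/flCD11cCre mice, each made from a pool of mice, per the series' design text. The droplets were made with a 10x Genomics 3' kit, so reads lie near the 3' ends of transcripts, per the labels' protocols. The deposited values are raw counts of UMIs per gene and barcode, made with Cell Ranger 7.0.0 per the file headers. The submitters' processing notes also name the mm10 genome, bcl2fastq, STAR, Seurat and R 4.3.0 without saying what each did. The annotation release, whether intronic reads were counted, and any removal of doublets before deposit are not given in the sources used here. The files hold 32285 genes and, in the same matrix, 5 antibody tags (CD11b, CD172a, MERTK, XCR1 and CD317), which were not foreseen and were left out of gene totals. The 12534 and 13820 barcodes hold 17306907 and 18118382 UMIs of tags in Stat4fl/flCD11cCre and WT. Groups were taken from the genotype in the labels.

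Barcodes with 500 or more genes, 1000 or more UMIs and under 10% mitochondrial UMIs were kept, 12305 in Stat4fl/flCD11cCre and 13298 in WT. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold, the planned setting, called 1785 cells (14.5%) in Stat4fl/flCD11cCre and 0 in WT, at scores of 0.154 and 0.697, so it did not work in WT. An alternative written before the data were examined, removal of the 10% of cells with the highest score in each library, was therefore used throughout, and 1231 and 1270 cells were removed. The automatic threshold was kept as an alternative that removes cells from 1 library only. Both libraries were merged without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without Stat4 and without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor variable and sex-linked genes, and 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters. A cluster took a class name, written as X-like, from marker genes fixed before the data were examined. It stayed unnamed with under 3 detected markers, where its leading genes were those of another class, or where it was shallow. Leading genes are the 10 with the highest fold over all other cells among genes found in 25% or more of the cluster's cells. Classes may still hold other cells: subclusters of the conventional DC-like class were made, and some were led by T cell, microglia or plasmacytoid DC genes.

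With 1 library per genotype no test across samples was possible. UMIs were summed per library and class and given as CPM, scaled to the UMIs of that class, with the exact Poisson interval, and ratios with the exact conditional binomial interval, at the 95% level. 7 classes with 200 or more cells in each library were compared. Shares carry exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts of the total allow. Shares of cells with a UMI and of cycling cells (3 or more proliferation genes found) were computed after thinning each cell to 2500 UMIs. Unthinned values are printed for cycling cells, for Il17a in T cell-like cells and for Il23r in T cell-like and conventional DC-like cells. Other unthinned shares with a UMI are not printed, except those of H2-Aa and Itgax, which were not thinned. For 22 gene lists fixed before the data were examined, the median log2 ratio of members with 50 or more UMIs was computed where 5 or more members were measured, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The text gives a part of these lists and classes, chosen after their values were seen.

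Genes are named by a rule fixed before the data were examined. Stat4, Il23r, Il12rb1, Il12rb2, Il12b, Il23a, Il12a, Il1b, Il6, Tnf and Flt3 are named where they have 10 or more UMIs. In each class the 6 highest and the 6 lowest ratios are named, ranked by the interval bound nearest to 1, among genes with 100 or more UMIs and 50 or more CPM in the higher library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor variable, sex-linked and predicted genes are left out of that ranking. For each list described, up to 4 members are named by the same rank, and clusters are described by their leading genes. Some genes chosen by these rules are not reported here. Of the always-named genes the text gives a part per class, and the IL-12 and IL-23 genes mainly as shares of cells; this narrowing was made after the values were seen.

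The ratio and interval step was tested on simulated data: counts were drawn from the real means of each class with 200 genes changed by known folds. Among 7232 genes of the conventional DC-like class, the direction was recovered for 88.2% of 1.5-fold, 93.6% of 2-fold and 100% of 4-fold changes, and 96.2% of intervals of unchanged genes held the true value. Among 5589 genes of the NK cell-like class, the direction was recovered for 85.3%, 97.4% and 100%. Such draws hold counting error only.

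The alternatives tried were a stricter cell filter (1000 genes, 5% mitochondrial UMIs) and a looser one (200 genes, 20%), no doublet removal, clustering resolutions 0.5 and 2, 15 principal components, clustering without the proliferation genes, clustering each library separately, median-of-ratios scaling, totals without mitochondrial and ribosomal protein genes, thinned cells, per-cell means, member minimums of 20 and 200 UMIs, unmatched random lists, thinning to 1000 UMIs, cycling thresholds of 2 and 5 genes, and for Stat4 all deposited barcodes. The automatic doublet threshold became an alternative after its result in WT was seen. Alternatives added after the data were seen were list medians of thinned cells, shares with microglia left out of the total, and the conventional DC-like class without its subclusters led by genes of other cells. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Gene positions are from the GENCODE annotation of GRCm38, the build also called mm10.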

Results

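Immune cells of the central nervous system were profiled one by one from mice with experimental autoimmune encephalomyelitis (EAE), a T cell-driven model of multiple sclerosis, on day 15 after immunization with a myelin peptide. Cells positive for MHC class II and CD11c, 2 surface proteins of antigen-presenting cells, were sorted from 1 pool of WT C57BL/6 mice and 1 pool of Stat4fl/flCD11cCre mice. In the latter, a Cre recombinase driven by the CD11c promoter is meant to delete Stat4, which passes on the signals of IL-12 and IL-23, from dendritic cells (DCs). Each genotype gave 1 library, so no difference here has a replicate check, no p-value is given, and every 95% interval covers counting error only. The WT library held 13820 barcodes with 122975017 UMIs (counted RNA molecules) of genes, and a median of 6228 per barcode. The Stat4fl/flCD11cCre library held 12534 barcodes with 120221740 UMIs of genes, and a median of 6767 per barcode. After the cell filter and the removal of likely doublets, 12028 WT cells (median 5974 UMIs) and 11074 Stat4fl/flCD11cCre cells (median 6301.5 UMIs) were compared. Changes are given from WT to Stat4fl/flCD11cCre, as CPM, the usual scaling of a gene's UMIs to the total of its cell class, and as the log2 ratio with its interval.

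The first comparison asked where Stat4 RNA was found and whether it fell in the library with the deletion. Stat4 (ENSMUSG00000062939) was highest in NK cell-like cells, at 416 CPM in WT (391 to 443) and 381 (356 to 408) in Stat4fl/flCD11cCre. It was 248 (239 to 257) and 227 (216 to 238) in T cell-like cells, both of them lymphocytes in which STAT4 carries the IL-12 signal, though the T cell ratio (log2 -0.13) reversed with the automatic doublet threshold. In conventional DC-like cells it was 73.2 (65.6 to 81.4) in WT and 74.5 (66.8 to 82.9) in Stat4fl/flCD11cCre, a log2 ratio of 0.03 (-0.20 to 0.25). It was 0.27 without the subclusters of that class led by T cell, microglia and plasmacytoid DC genes, and 0.30 with the automatic doublet threshold. Over all cells used it went from 59.6 to 40.3 (log2 -0.56, -0.62 to -0.50), while the share of Stat4-rich T cell-like cells was lower. The labels do not say which exons of Stat4 are floxed, and 3' reads from outside a deleted part check nothing, so these values do not test the deletion. Gamma-delta T or innate lymphoid cell-like cells had 262 and 226 CPM of Stat4 (log2 -0.21, -0.59 to 0.16). B cell-like cells had 75.1 and 48.0 (log2 -0.65, -1.06 to -0.24) and plasmacytoid DC-like cells 34.4 and 38.7. Neutrophil-like cells had 51.2 and 54.6 CPM of Stat4, monocyte-like cells 16.8 and 9.79, inflammatory macrophage-like cells 12.1 and 10.7, and microglia-like cells 4.22 and 1.79, the lowest of these classes. The log2 ratio in the macrophage class moved from -0.18 to -1.37 with the automatic doublet threshold, and in microglia from -1.24 to -0.48 with no doublets removed.

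The next comparison asked which cell classes made up the sorted cells, since the series title speaks of an expansion of classical DCs. Microglia-like cells, the resident macrophages of the brain, took 24.7% of WT cells (24.0 to 25.5) and 43.8% of Stat4fl/flCD11cCre cells (42.9 to 44.8), a ratio of 1.77 (1.69 to 1.86). T cell-like cells went from 17.2% to 8.24% (ratio 0.480, 0.444 to 0.519), and B cell-like cells from 1.92% to 0.903% (ratio 0.470, 0.368 to 0.597). Inflammatory macrophage-like cells, led by Arg1 and Slc7a2, went from 27.8% to 17.04% (ratio 0.612, 0.578 to 0.648). Conventional DC-like cells went from 4.61% to 3.60% (ratio 0.782, 0.686 to 0.891), but with microglia left out of the total they were 6.12% and 6.41% (ratio 1.05, 0.919 to 1.19). NK cell-like cells behaved alike, from 4.02% to 3.12% (ratio 0.776, 0.674 to 0.893) and a ratio of 1.04 (0.903 to 1.20) without microglia, though their share rose when the libraries were clustered separately. Plasmacytoid DC-like cells took 1.46% and 1.38%, and gamma-delta T or innate lymphoid cell-like cells 0.823% and 0.713%, with both ratios' intervals spanning 1. Neutrophil-like cells went from 6.90% to 9.89% (ratio 1.43, 1.31 to 1.57). That ratio was nearer 1 with clustering resolution 2.0, with 15 principal components and with either changed cell filter, as given below. It also leaves out an unnamed cluster with genes of mature neutrophils, described next, whose share went the other way. The monocyte-like share, 5.23% and 6.84% (ratio 1.31, 1.17 to 1.46), changed direction with clustering resolution 2.0, with 15 principal components and with the stricter cell filter.

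3 clusters stayed unnamed, and their leading genes are those of known cells outside the DC gate. A cluster led by Elane, Ctsg and Mpo, granule proteins of immature myeloid cells, took 1.27% of WT cells and 2.40% of Stat4fl/flCD11cCre cells. Another led by Steap4, Hdc and Cxcr2, genes of mature neutrophils, took 2.94% and 1.13%, opposite to the neutrophil-like class. The last, led by Ttr and Enpp2, genes of the choroid plexus that makes cerebrospinal fluid, took 1.09% and 0.795%. 1 WT cell and 14 Stat4fl/flCD11cCre cells were endothelial or stromal-like. By the series' design all cells passed an MHC class II and CD11c gate, so shares would depend on surface levels of those proteins. An H2-Aa UMI was found in 73.8% of microglia-like WT cells and 20.3% of those of Stat4fl/flCD11cCre, though their share rose. Itgax, which encodes CD11c, had a UMI in 10.8% and 4.97% of microglia-like and 6.87% and 5.70% of T cell-like cells. In conventional DC-like cells it was 29.4% and 40.6%. RNA does not measure surface protein, so how strictly the gate held was not tested. Median depth also differed by class, from 7682.5 UMIs in WT to 10439 in Stat4fl/flCD11cCre for conventional DC-like cells and from 4341.5 to 5001 for microglia-like cells.

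**Figure D1:**
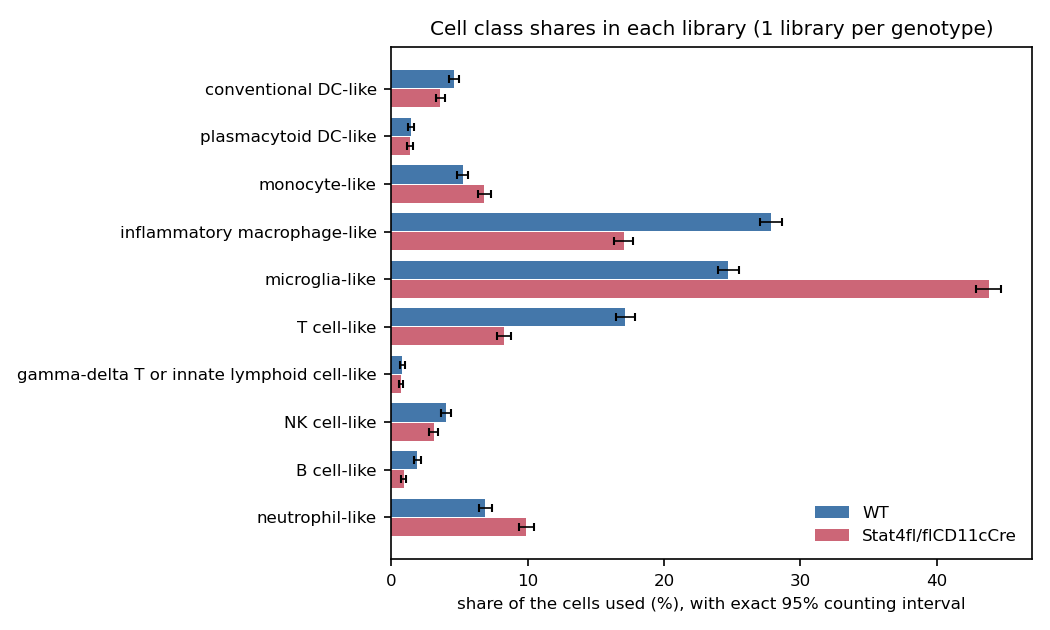
Share of the cells used (%) in 10 cell classes of the WT and Stat4fl/flCD11cCre libraries, 1 library each; bars are shares and whiskers exact 95% counting intervals. Microglia-like cells take 24.7% and 43.8%, and T cell-like cells 17.2% and 8.24%.

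Conventional DC-like cells present antigen to T cells, and the question was whether their antigen presentation and activation programmes differed. Genes induced by interferon-gamma were lower in Stat4fl/flCD11cCre. Iigp1, a GTPase against vacuolar pathogens, went from 109 to 38.3 CPM (log2 -1.51, -1.77 to -1.26), and Cxcl9, a chemokine for activated T cells, from 277 to 103 (log2 -1.43, -1.59 to -1.28). The median of the interferon-gamma response list was -0.46 (below all 10000 random lists). Without the subclusters led by T cell, microglia and plasmacytoid DC genes it was -0.29, so the cells of those subclusters carry part of it. The type I interferon response list had a median of -0.43 (below all 10000 random lists), and -0.29 without those subclusters. Isg15 went from 352 to 224 (log2 -0.65, -0.77 to -0.54), Ifit2 from 42.5 to 21.5 (log2 -0.99, -1.35 to -0.63) and Irf7 from 210 to 136 (log2 -0.63, -0.78 to -0.49). Ly6c2 and Ly6i, surface proteins of inflammatory monocytes, went from 433 to 217 (log2 -0.998, -1.11 to -0.89) and from 78.1 to 34.3 (log2 -1.19, -1.47 to -0.91). The heat-shock genes Hspa1b and Hspa1a also fell, from 847 to 320 (log2 -1.40, -1.49 to -1.32) and from 770 to 322 (log2 -1.26, -1.35 to -1.17).

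Costimulation, homing, cholesterol synthesis and MHC class II lists were slightly higher in conventional DC-like cells of Stat4fl/flCD11cCre, as were genes that respond to tissue handling. In that order, 2 of 10, 2 of 14, 1 of 13 and 0 of 12 measured members were 1.5-fold or more higher, and 0 were 1.5-fold or more lower. The dendritic cell development list had a median of -0.05 (percentile 17.5). The dissociation stress list of immediate-response and heat-shock genes had a median of 0.50 (above all 10000 random lists). That is larger than the costimulation, homing, cholesterol synthesis and MHC class II medians. Nr4a1 (0.87, 0.73 to 1.02) and Egr1 (0.87, 0.69 to 1.05) rose while its members Hspa1a and Hspa1b fell. Costimulatory ligands had a list median of 0.26 (percentile 99.99), and 0.232 (-0.0489 to 0.404) with thinned cells. Tnfsf9 went from 53.2 to 107 (log2 1.005, 0.78 to 1.23), Cd80 from 32.6 to 55.1 (log2 0.76, 0.46 to 1.06), Cd86 from 250 to 353 (log2 0.50, 0.39 to 0.61) and Cd83 from 205 to 289 (log2 0.49, 0.37 to 0.62). The lymph node homing and adhesion list had a median of 0.29 (above all 10000 random lists). Ccr7, the receptor that takes mature DCs to lymph nodes, went from 5.37 to 23.9 (log2 2.15, 1.52 to 2.84) and Itgam, which encodes CD11b, from 105 to 152 (log2 0.54, 0.37 to 0.71). The cholesterol synthesis list had a median of 0.31 (percentile 99.98), and 0.143 (-0.0976 to 0.368) with thinned cells. Its member Msmo1 went from 49.4 to 74.1 (log2 0.59, 0.34 to 0.83). The MHC class II list had a median of 0.14 (percentile 99.6). The log2 ratios of H2-Aa (0.22, 0.20 to 0.24), H2-Ab1 (0.19, 0.17 to 0.21) and H2-Eb1 (0.22, 0.20 to 0.25) were small. Il1b, which encodes an inflammatory cytokine, went from 1206 to 1726 (log2 0.52, 0.47 to 0.57). Tnf (-0.23, -0.57 to 0.11), Il6 (-0.35, -1.03 to 0.31) and Flt3 (-0.12, -0.29 to 0.05), the last the growth-factor receptor of DCs, had intervals that span 0. Il12rb2, a chain of the IL-12 receptor, went from 14.4 to 8.41 (log2 -0.77, -1.39 to -0.18). Without the T cell-led and microglia-led subclusters, an Il12rb2 UMI was found in 2.66% and 3.14% of thinned cells (ratio 1.18, 0.472 to 2.92). A fall of Il12rb2 in DCs themselves is thus not settled. The genes that rose most by the fixed rule were Plcb1 (1.98, 1.57 to 2.42), Plcb4 (1.75, 1.41 to 2.09) and the choroid plexus gene Ttr (1.82, 1.58 to 2.08). They were followed by Mgl2 (1.26, 1.11 to 1.41), a lectin of conventional DCs, Cox6a2 (1.33, 1.04 to 1.63) and the lipid carrier Apoe (1.11, 1.03 to 1.20). Mgl2 and Apoe are each among the leading genes of a subcluster that took more of the class in Stat4fl/flCD11cCre, as described next. How much of the rises in this class comes from its make-up was not tested. Cox6a2 changed direction when subclusters led by plasmacytoid DC, T cell and microglia genes were left out, and both Cox6a2 and Apoe when doublets were removed at the automatic threshold.

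Subclusters of the conventional DC-like class were compared to ask whether a DC subset was lost. The cDC1-like subcluster, led by Xcr1, Gcsam and Clec9a, which mark DCs that cross-present antigen, took 24.4% of the class in WT (20.8 to 28.2) and 18.0% in Stat4fl/flCD11cCre (14.4 to 22.2), a ratio of 0.741 (0.548 to 0.993). An unnamed subcluster led by Creb5, Ccl17 and C3, with Apoe also among its leading genes, took 17.3% and 23.6%. Another led by Kcne3, Cxcl10 and Clec4b1 took 21.7% and 23.6%, and another led by Mgl2, Sh2d1b1 and Cd72 took 8.84% and 11.3%. A subcluster led by Cd3e and Trbc2, T cell genes, took 10.7% and 7.02%. A plasmacytoid DC-like one took 12.5% and 12.8%, and one with microglia genes took 4.69% and 3.76%, so the class is not pure. Cycling cells, those with 3 or more proliferation genes after each cell was thinned to 2500 UMIs, were 5.05% of the class in WT (27 of 535 cells) and 4.07% in Stat4fl/flCD11cCre (16 of 393 cells). The ratio was 0.807 (0.406 to 1.55), and 0.302 with 5 or more genes. Unthinned, they were 16.1% and 17.3%. The proliferation list had a median of -0.17 (percentile 5.62) and few cells were cycling, so a difference in DC proliferation was not settled at this depth. The separate-clustering and no-doublet-removal alternatives gave that list the opposite sign.

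Which cells carried the IL-12 and IL-23 machinery was asked next, because the series title places IL-23 upstream of STAT4. After thinning to 2500 UMIs, Il23r, the IL-23 receptor, was found in 52.1% of gamma-delta T or innate lymphoid cell-like cells in WT (41.6 to 62.4) and 57.1% in Stat4fl/flCD11cCre (45.4 to 68.4). In T cell-like cells it was 3.44% (2.67 to 4.36) and 5.30% (3.92 to 6.99), unthinned 6.34% and 11.5%. Among conventional DC-like cells Il23r was found in 0 of 535 WT cells, which allows up to 0.561% of cells with a UMI at this depth and does not exclude expression below it, and in 1 of 393 Stat4fl/flCD11cCre cells. Unthinned it was found in 3 of 554 and 6 of 399, in a class that includes the subcluster with T cell genes. No thinned microglia-like cell had an Il23r UMI (0 of 2646 in WT, which allows up to 0.113% at this depth, and 0 of 4610), at median depths of 4341.5 and 5001 UMIs against 7682.5 and 10439 in conventional DC-like cells. Il12b, the subunit shared by IL-12 and IL-23, was found in 0.945% of microglia-like WT cells (0.612 to 1.39) and 0.0651% in Stat4fl/flCD11cCre (0.0134 to 0.190). It was found in 0.440% and 0.162% of inflammatory macrophage-like cells. Il12rb1, a receptor chain shared by both cytokines, was found in 1.06% and 0.260% of microglia-like cells. Il12b was also found in 2 of 535 and 1 of 393 conventional DC-like cells, and in none of 1916 and 886 T cell-like cells, with medians of 4952.5 and 5940 UMIs. Il23a, the other subunit of IL-23, was found in 1.54% and 0.810% of inflammatory macrophage-like cells. Il12a, the other subunit of IL-12, was found in 8.67% and 9.15% of plasmacytoid DC-like cells. Il12rb2, the IL-12 receptor chain, was found in 33.4% and 33.6% of NK cell-like cells, 14.8% and 11.3% of T cell-like cells and 3.55% and 3.05% of conventional DC-like cells. Stat4 itself was found in 40.4% and 41.2% of T cell-like, 57.2% and 55.6% of NK cell-like and 14.6% and 13.2% of conventional DC-like cells, against 0.567% and 0.108% of microglia-like cells. The DC values include cells of the subclusters with genes of other cells. Without those led by T cell, microglia and plasmacytoid DC genes, Stat4 was found in 11.3% and 13.3% and Il12rb2 in 2.56% and 2.99% of conventional DC-like cells. Cells under 2500 UMIs were left out, 10.6% in WT and 6.87% in Stat4fl/flCD11cCre.

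Microglia-like cells were compared as the most abundant class of the Stat4fl/flCD11cCre library. Mitochondrial genes took 1.89% of its UMIs in WT and 1.30% in Stat4fl/flCD11cCre, and ribosomal protein genes 10.95% and 8.01%, so RNA make-up also differed. Antigen presentation genes were far lower there. Cd74, the chaperone of MHC class II, went from 4189 to 792 CPM (log2 -2.40, -2.42 to -2.38) and H2-Aa from 1288 to 236 (log2 -2.45, -2.49 to -2.41). H2-Eb1 went from 1091 to 203 (log2 -2.43, -2.47 to -2.38), H2-Ab1 from 1494 to 295 (log2 -2.34, -2.38 to -2.31) and Ciita, their shared activator, from 42.1 to 7.45 (log2 -2.50, -2.72 to -2.28). The MHC class II list had a median of -0.96 (below all 10000 random lists). Interferon-gamma response genes had a median of -1.62 (below all 10000 random lists). Cxcl9 went from 241 to 45.7 (log2 -2.40, -2.49 to -2.31) and Iigp1 from 334 to 74.4 (log2 -2.17, -2.24 to -2.10). Type I interferon genes had a median of -1.38 (below all 10000 random lists), and Oasl2 among them went from 96.4 to 29.4 (log2 -1.71, -1.84 to -1.59). The T cell chemokine Ccl5 went from 359 to 61.0 (log2 -2.56, -2.63 to -2.48), Il12b from 13.6 to 2.19 (log2 -2.63, -3.05 to -2.23), Tnf from 113 to 62.2 (log2 -0.86, -0.95 to -0.76) and Il1b from 114 to 57.1 (log2 -1.004, -1.10 to -0.91). The list of damage-associated and phagocyte genes had a median of -0.83 (below all 10000 random lists). Apoe went from 5568 to 2272 (log2 -1.29, -1.31 to -1.28), Cst7, a protease inhibitor of activated microglia, from 125 to 39.7 (log2 -1.66, -1.76 to -1.55) and the phagocytic receptor Axl from 73.8 to 25.3 (log2 -1.54, -1.68 to -1.41). Gpr34, a receptor of resting microglia, rose from 596 to 1338 (log2 1.17, 1.13 to 1.20), Qpct from 7.20 to 52.0 (log2 2.85, 2.58 to 3.14) and Fscn1 from 66.3 to 157 (log2 1.24, 1.15 to 1.34). So did Thrsp (1.27, 1.12 to 1.43), Upk1b (1.38, 1.21 to 1.55) and Abcb4 (1.38, 1.21 to 1.55). Top2a, a replication gene, went from 81.5 to 30.1 (log2 -1.44, -1.56 to -1.31) and the proliferation list had a median of -1.08 (below all 10000 random lists). Cycling cells went from 9.90% to 2.99% of thinned cells (ratio 0.302, 0.244 to 0.373; unthinned 15.0% and 6.43%). The class differed in make-up. A cluster led by Ccl12, C4b, Cst7 and Iigp1 held 55.7% of the class in WT and 12.9% in Stat4fl/flCD11cCre. One led by Dlc1, Abcb4, Upk1b and Gpr34 held 19.0% and 49.8% and one led by Gpr34, Slc2a5 and Fscn1 held 14.8% and 28.0%. The free RNA list, which holds haemoglobin, neutrophil and myelin genes, had a median of 0.96 (above all 10000 random lists) over members that moved apart. Hba-a2 went from 0.993 to 57.4 (log2 5.85, 5.15 to 6.66), Hbb-bs from 4.53 to 183 (log2 5.34, 5.004 to 5.69) and Hba-a1 from 1.92 to 79.3 (log2 5.37, 4.86 to 5.93), while S100a9 fell from 89.5 to 67.9 (log2 -0.40, -0.50 to -0.30). With the automatic doublet threshold the haemoglobin genes fell instead, and S100a9 reversed under 3 alternatives. Dissociation stress genes had a median of -0.03 (percentile 15.4). The median of all genes in the class was 0.10.

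**Figure D2:**
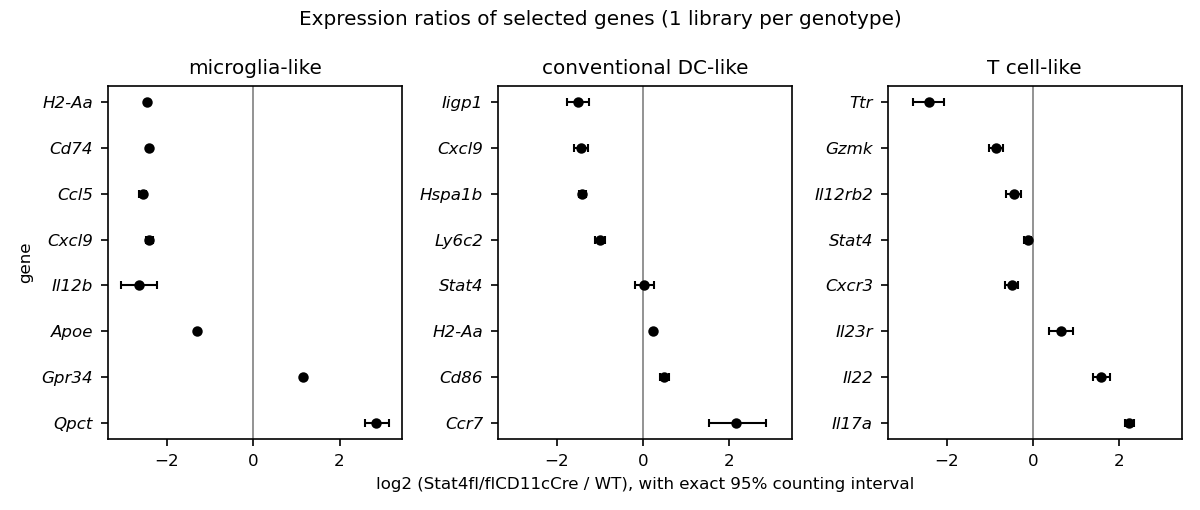
Log2 ratio of CPM, Stat4fl/flCD11cCre over WT, for 8 genes in each of 3 cell classes; points are ratios and whiskers exact 95% counting intervals. H2-Aa is at -2.45 in microglia-like cells and 0.22 in conventional DC-like cells, and Il17a is at 2.23 in T cell-like cells.

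Inflammatory macrophage-like cells, which derive from blood monocytes in EAE, were compared for the cytokines and interferon genes of tissue damage. Tnf went from 236 to 107 CPM (log2 -1.14, -1.20 to -1.08) and Nos2, which makes nitric oxide, from 66.6 to 37.3 (log2 -0.84, -0.94 to -0.73). Il23a went from 7.21 to 3.49 (log2 -1.05, -1.40 to -0.71) and Il12b from 4.47 to 0.690 (log2 -2.69, -3.48 to -1.99). Il1b went the other way, from 1693 to 2201 (log2 0.38, 0.36 to 0.39), though it reversed when each library was clustered on its own. The interferon-gamma response list had a median of -0.56 (below all 10000 random lists). Iigp1 went from 204 to 95.1 (log2 -1.10, -1.17 to -1.04) and Gbp5, an inflammasome GTPase, from 202 to 103 (log2 -0.97, -1.04 to -0.91). The type I interferon list had a median of -0.40 (below all 10000 random lists), and Oasl1 went from 59.2 to 28.1 (log2 -1.08, -1.20 to -0.96). Mrc1, the mannose receptor of tissue-repair macrophages, rose from 30.0 to 75.7 (log2 1.34, 1.23 to 1.44), Fabp5, a lipid carrier, from 573 to 1058 (log2 0.88, 0.86 to 0.91) and Thbs1 from 171 to 329 (log2 0.94, 0.90 to 0.99), the last reversed under separate clustering. The immediate-response genes Nr4a2 (1.04, 0.95 to 1.12) and Nr4a3 (0.93, 0.85 to 1.02) and the signalling gene Plcb4 (3.57, 3.37 to 3.77) rose too. The neutrophil proteins S100a9 (-2.29, -2.33 to -2.25), S100a8 (-2.10, -2.14 to -2.07), Lcn2 (-2.37, -2.54 to -2.20) and Retnlg (-2.61, -2.76 to -2.47) led the genes that fell, with Hdc (-1.39, -1.52 to -1.27) and Hspa1b (-1.30, -1.35 to -1.26). Retnlg rose under separate clustering. The free RNA list had a median of -2.10 (below all 10000 random lists). The proliferation list had a median of -0.93 (below all 10000 random lists) that reversed under separate clustering. Top2a went from 23.03 to 8.86 (log2 -1.38, -1.59 to -1.17), and cycling cells were 3.27% and 1.51% of thinned cells (ratio 0.462, 0.293 to 0.707; unthinned 20.9% and 14.7%). That ratio was 0.890 with 5 or more genes and 0.261 with the automatic doublet threshold. The MHC class II list had a median of 0.02 (percentile 64.9). Dissociation stress genes had a median of 0.17 (percentile 99.95) that reversed under separate clustering and with the automatic doublet threshold. The class differed in make-up. A cluster led by Cxcl2, Il6 and Il1b went from 19.9% to 26.7% of the class and one led by Slc7a2, Arg1 and Nos2 from 32.9% to 21.5%, which bears on the rise of Il1b and the fall of Nos2. One led by Arg1, Slc7a2 and Fabp5 held 47.2% and 51.8%.

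Monocyte-like cells lay mostly in a cluster with genes of patrolling monocytes, described below. In this class the interferon-gamma response list had a median of -1.19 (below all 10000 random lists), -0.90 with thinned cells and -2.76 under separate clustering. Cxcl9 went from 952 to 338 CPM (log2 -1.49, -1.57 to -1.42), Iigp1 from 258 to 89.7 (log2 -1.52, -1.66 to -1.39) and the protease inhibitor Serpina3g from 109 to 36.8 (log2 -1.57, -1.79 to -1.35). Ccl5 went from 335 to 72.3 (log2 -2.21, -2.36 to -2.07), Tnf from 95.9 to 40.0 (log2 -1.26, -1.48 to -1.05) and Upp1, a uridine-degrading enzyme, from 111 to 40.7 (log2 -1.44, -1.66 to -1.23), while Il1b stayed at 1121 to 1114 (log2 -0.01, -0.06 to 0.04). Type I interferon genes had a median of -0.62 (below all 10000 random lists), and -2.12 under separate clustering. Isg15 went from 640 to 345 (log2 -0.89, -0.97 to -0.81) and Ifit2 from 154 to 73.8 (log2 -1.06, -1.23 to -0.90). The MHC class II list had a median of -0.36 (percentile 0.03), which was -0.11 with the automatic doublet threshold and -0.85 under separate clustering. The genes that rose most by the fixed rule were the immediate-response gene Nr4a2 (1.58, 1.26 to 1.92) and Itgax, which encodes CD11c and went from 20.04 to 56.6 (log2 1.498, 1.17 to 1.84). Next came the immediate-response genes Fos (1.01, 0.95 to 1.08) and Dusp1 (0.88, 0.78 to 0.98), the polarity gene Mpp7 (0.94, 0.71 to 1.17) and Nr4a1 (0.82, 0.70 to 0.93). The dissociation stress list, which holds Fos, Nr4a1 and Dusp1, had a median of 0.30 (above all 10000 random lists) that reversed with the automatic doublet threshold. Itgax reversed with clustering resolution 2.0, separate clustering and the stricter cell filter, and Dusp1 lost its rise with the automatic doublet threshold. Ttr, a choroid plexus gene, fell (-2.98, -3.36 to -2.62). The proliferation list had a median of 0.27 (percentile 97.9), and 3.67% and 4.27% of thinned cells were cycling (unthinned 9.70% and 13.3%). That median was 4.32 under separate clustering and 0.00693 with the automatic doublet threshold, so its size is not settled. A cluster led by Cd300e, Ace and Treml4, genes of patrolling monocytes, held 57.7% of the class in WT and 78.3% in Stat4fl/flCD11cCre, and one led by Cxcl10 and Rsad2 the rest.

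Neutrophil-like cells are short-lived granulocytes that also respond to interferon-gamma. Their list median for that response was -1.24 (below all 10000 random lists) and -0.57 with thinned cells, against -0.20 for the median of all genes in the class. Iigp1 went from 54.5 to 5.84 CPM (log2 -3.22, -3.85 to -2.64), Tgtp1 from 83.7 to 13.9 (log2 -2.59, -3.00 to -2.20) and Gbp4 from 62.1 to 10.1 (log2 -2.62, -3.11 to -2.16), all GTPases against intracellular pathogens. Tnf went from 424 to 133 (log2 -1.67, -1.81 to -1.53) and Il23a from 16.96 to 4.43 (log2 -1.94, -2.74 to -1.18). Traf1, an adaptor of TNF receptors, went from 89.5 to 19.1 (log2 -2.23, -2.58 to -1.88), Calhm6 from 52.3 to 12.7 (log2 -2.04, -2.49 to -1.61) and Hspa1b from 170 to 49.3 (log2 -1.79, -2.02 to -1.56). Il1b was 2531 to 2956 (log2 0.22, 0.18 to 0.26) and reversed under separate clustering. The type I interferon list had a median of -0.97 (below all 10000 random lists). Ifit2 went from 76.5 to 23.6 (log2 -1.70, -2.04 to -1.37) and Rsad2 from 304 to 134 (log2 -1.18, -1.33 to -1.03). The MHC class II list had a median of -1.12 (below all 10000 random lists), and Cd74 went from 766 to 325 (log2 -1.24, -1.33 to -1.14). That median was -3.39 with the automatic doublet threshold and -1.85 under separate clustering. Mitochondrial genes took 0.908% and 0.539% of the UMIs of the class and ribosomal protein genes 6.32% and 4.49%. The dissociation stress list had a median of -0.41 (percentile 1.99) and complement genes -0.68 (percentile 0.2), both reversed under separate clustering. Cxcl3, a neutrophil chemokine, rose from 15.9 to 61.0 (log2 1.94, 1.48 to 2.43), and the granule genes Olfm4 (1.22, 0.93 to 1.53) and Retnlg (0.85, 0.83 to 0.86) rose with it. So did Cdc42ep3 (1.16, 0.89 to 1.44), Cd244a (1.13, 0.76 to 1.51) and Csmd3 (1.997, 1.55 to 2.47), the last a microglia cluster gene that reversed under 3 alternatives. A cluster led by Retnlg, Ly6g and Ltf held 27.7% of the class in WT and 49.0% in Stat4fl/flCD11cCre, and one led by Il1f9 and Cxcr2 the rest. The unnamed cluster led by Steap4, Hdc and Cxcr2, with 354 WT and 125 Stat4fl/flCD11cCre cells, was not part of these comparisons. Cycling cells were 11 of 351 and 3 of 685 thinned cells (3.13% and 0.438%; unthinned 2.65% and 0.913%).

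T cell-like cells were compared because STAT4 in antigen-presenting cells is proposed to shape the T cells that cause EAE. Il17a, the cytokine of Th17 cells, rose from 89.8 to 421 CPM (log2 2.23, 2.13 to 2.33) and Il22, another Th17 cytokine, from 29.3 to 87.6 (log2 1.58, 1.39 to 1.77). Il23r went from 18.8 to 29.6 (log2 0.66, 0.38 to 0.93). The receptor gene Il12rb2 went from 78.1 to 57.2 (log2 -0.45, -0.62 to -0.28), Cxcr3, a homing receptor of activated T cells, from 102 to 72.6 (log2 -0.49, -0.64 to -0.34) and Gzmk, a granzyme of CD8 T cells, from 102 to 56.3 (log2 -0.86, -1.02 to -0.69). Tnfrsf9, a costimulatory receptor, went from 188 to 94.6 (log2 -0.99, -1.12 to -0.87) and Ly6c2 from 525 to 277 (log2 -0.92, -0.996 to -0.85). The list of STAT4-linked effector genes as a whole had a median of -0.04 (percentile 6.52). Of its 11 measured members, 3 were 1.5-fold or more higher, Il17a among them, 0 were 1.5-fold or more lower and 8 lay between. The interferon-gamma response list was at -0.01 (percentile 16.4), and -0.25 with no doublets removed, while the type I interferon list had a median of -0.40 (below all 10000 random lists), with Ifit3 moving from 40.2 to 19.3 (log2 -1.06, -1.34 to -0.78). Tnf went from 137 to 169 (log2 0.30, 0.19 to 0.41) but reversed with thinned cells and with per-cell means. Hist1h2ap, a histone gene, fell (-1.08, -1.15 to -1.01) with Ttr (-2.40, -2.77 to -2.06). Plcb4 (1.12, 0.98 to 1.26), Wdfy1 (1.43, 1.20 to 1.67), S100a9 (1.51, 1.35 to 1.68) and Cst3 (1.10, 1.04 to 1.15) rose. The last 2, genes of neutrophils and microglia, reversed with the automatic doublet threshold. So did the medians of the free RNA list, 1.47 (above all 10000 random lists), and of the complement list, 0.59 (percentile 99.99). Cycling cells were 19.0% and 18.8% of thinned cells (unthinned 29.3% and 33.5%). The proliferation list had a median of 0.02 (percentile 31.1), and the MHC class II list 0.04 (percentile 54.9). The latter turned to -0.23 with no doublets removed, -0.18 with thinned cells and -1.74 with the automatic doublet threshold. Dissociation stress genes had a median of 0.04 (percentile 61.7) that reversed with the automatic doublet threshold. The class also differed in make-up. A cluster led by Cd8b1 and Gzmk, which bears on the fall of Gzmk, went from 22.3% to 15.9% of the class and one led by Foxp3 from 14.8% to 18.5%. One led by Tnfsf11, Cd40lg and Ifng held 54.9% and 57.5%, and one led by histone genes 8.08% and 8.11%.

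NK cell-like cells are the class with the most Stat4 RNA. Ifng, the gene of interferon-gamma, went from 155 to 92.8 CPM (log2 -0.74, -0.99 to -0.49) and Csf2, which encodes the growth factor GM-CSF, from 67.2 to 5.77 (log2 -3.54, -4.48 to -2.73). Ccl1 went from 117 to 2.66 (log2 -5.46, -6.91 to -4.32) and Tnf from 44.5 to 8.43 (log2 -2.40, -3.19 to -1.69). Il18r1, a receptor chain induced by STAT4, went from 253 to 195 (log2 -0.37, -0.55 to -0.19), and the STAT4-linked list had a median of -0.16 (percentile 0.24). The counting interval of that median spans 0 (-0.333 to 0.0552), and its sign turned with no doublets removed and with members of 200 or more UMIs. The granzymes Gzmf and Gzmd, killing proteins of stimulated NK cells, rose from 1.62 to 115 (log2 6.15, 4.78 to 8.04) and from 10.5 to 63.9 (log2 2.60, 1.99 to 3.27). Mki67 went from 63.9 to 153 (log2 1.26, 0.98 to 1.54) and Cdk1, the kinase of mitosis, from 24.3 to 67.0 (log2 1.46, 1.02 to 1.92). The proliferation list had a median of 0.84 (above all 10000 random lists), which was 2.85 under separate clustering and 0.68 with thinned cells, and cycling cells went from 8.24% to 13.9% of thinned cells (ratio 1.69, 1.06 to 2.70; unthinned 15.5% and 20.6%). Itgad, an integrin chain, rose from 4.86 to 85.2 (log2 4.13, 3.30 to 5.11) and Cox6a2, a mitochondrial subunit of plasmacytoid DCs, from 10.9 to 112 (log2 3.36, 2.78 to 3.99). Plcb4 (2.85, 2.38 to 3.34) and Tanc2 (1.65, 1.15 to 2.18) rose too, the last reversed with the automatic doublet threshold. MHC class II genes, which belong to antigen-presenting cells, had a median of -1.57 (below all 10000 random lists). Its size depends on the settings, from -0.32 with no doublets removed to -2.30 with members of 200 or more UMIs. Lower were H2-Eb1 (-2.82, -3.41 to -2.28), H2-Aa (-2.40, -2.93 to -1.91), Cd74 (-2.32, -2.61 to -2.03) and H2-Ab1 (-2.28, -2.70 to -1.88). The interferon-gamma response list had a median of 0.03 (percentile 24.1) and the type I interferon list -0.18 (percentile 0.615). The former fell to -0.47 with no doublets removed and to -0.70 with the automatic doublet threshold, so a lower interferon-gamma response in this class is not excluded. The latter, whose counting interval spans 0, had the opposite sign under separate clustering. Dissociation stress genes had a median of -0.16 (percentile 0.02).

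**Figure D3:**
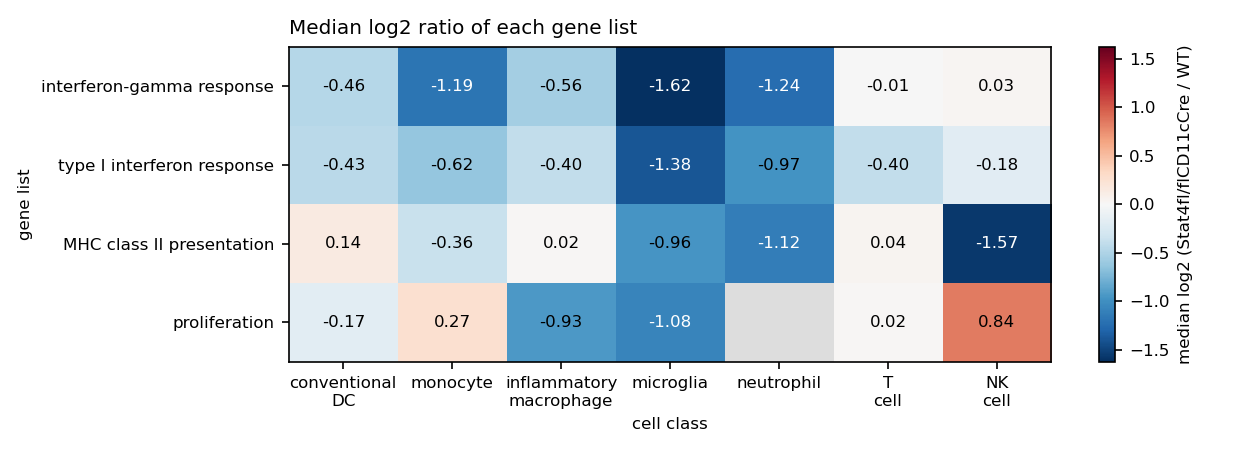
Median log2 ratio of 4 gene lists, chosen after their values were seen, Stat4fl/flCD11cCre over WT, by cell class, 1 library per genotype; colour and number give the median, and the grey cell had too few measured members. The interferon-gamma response is at -1.62 in microglia-like cells, -0.46 in conventional DC-like cells and -0.01 in T cell-like cells.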

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

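The antibody tags were not foreseen, so their comparison was chosen only after the files were seen, and the list medians below were set side by side after they were computed.

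Proliferation genes moved in opposite directions between cell classes. The list median was 0.841 in NK cell-like cells, where Mki67 and Cdk1 rose, and -0.926 in inflammatory macrophage-like and -1.08 in microglia-like cells, where Top2a fell. The difference between classes was not tested, and the macrophage value reversed to 0.26 when each library was clustered on its own.

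Complement genes, which tag targets for phagocytes, had a median of 0.589 in T cell-like cells and -0.678 in neutrophil-like cells. The free RNA list of haemoglobin, neutrophil and myelin genes had a median of 1.47 in T cell-like and 0.957 in microglia-like cells against -2.10 in inflammatory macrophage-like cells, where S100a8, S100a9 and Retnlg fell. In microglia-like cells the members moved apart, as haemoglobin genes rose and S100a9 fell. These differences were not tested. The T cell value of the complement list reversed to -0.24 with no doublets removed and to -2.99 with the automatic doublet threshold, which also turned the T cell value of the free RNA list to -4.50. The neutrophil value of the complement list reversed to 0.24 under separate clustering, so these contrasts do not hold under all settings, and no biological explanation was tested for either list.

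The antibody tags carried signal above T cell-like cells, which should lack most of these proteins. Over both libraries, the median of CD11b tag UMIs was 44.9 times that of T cell-like cells in inflammatory macrophage-like cells, that of CD172a 8.96 times, that of MERTK 4.31 times and that of XCR1 3.86 times. In WT and Stat4fl/flCD11cCre on their own these were 39.9 and 58.4 times for CD11b, 10.2 and 5.84 for CD172a, 4.50 and 2.91 for MERTK and 4.09 and 2.80 for XCR1. CD317, a surface protein of plasmacytoid DCs, was 13.5 times the T cell level in plasmacytoid DC-like cells, 15.2 and 10.1 times with medians of 197 and 212 UMIs in WT and Stat4fl/flCD11cCre. XCR1, a marker of cross-presenting DCs, was 1.27 and 1.24 times the T cell level in conventional DC-like cells of WT and Stat4fl/flCD11cCre, and its highest class was the inflammatory macrophage-like one. Its median over both libraries was 32 UMIs in the cDC1-like subcluster and 30 in the microglia-led one, pooled over libraries that differ in tag level, so whether the tag marks these cells was not settled. The T cell-like level itself differed between libraries, with medians of 40 and 94 UMIs for CD172a, 12 and 33 for MERTK and 11 and 25 for XCR1 in WT and Stat4fl/flCD11cCre. Tag levels were therefore not compared between genotypes.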

How the results depend on the processing

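The list medians of thinned cells, the shares without microglia and the conventional DCs without some subclusters were chosen only after the data were seen. The automatic doublet threshold was planned as the main setting and became an alternative after its result in WT was seen; every other alternative was planned. Most directions held. Of 146 named gene ratios, 142 had an interval that excludes 0, and their direction was kept in 1453 of 1478 values under alternatives. Many of these genes were named because their interval lies far from 0, so these counts are partly fixed by the choice. Alternatives that change only the scaling shift all genes of a class alike and can reverse few of them. Of 45 list medians, 35 had an interval that excludes 0, and the direction was kept in 242 of 252. Of 10 class shares, 8 did, and 73 of 79 were kept. For shares of cells with IL-12 family genes 20 of 20 were kept, for cycling shares 19 of 19 and for Stat4 8 of 9. The interferon-gamma list in conventional DCs, monocytes, macrophages, microglia and neutrophils was negative under every alternative run. The monocyte share, Itgax in monocytes, Csmd3 in neutrophils and S100a9 in microglia each reversed under 3 alternatives, more than any other result whose interval excludes 0 or, for shares, 1. The values below are those that reversed, and the list, share, cycling and Stat4 values that moved beyond counting error. Names stand for the X-like classes, macrophages for the inflammatory macrophage-like class. The cause was not tested, except that the automatic threshold removes cells from Stat4fl/flCD11cCre only, that the subclusters left out take their own genes with them, and that leaving microglia out changes only the total. Depth limits rare genes and small classes: for Il12b and Il23r in conventional DCs the counts were too few to compare, and most WT neutrophils (57.7%) were too shallow to thin.

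With clustering resolution 0.5, the share ratio was 1.79 for monocytes. With clustering resolution 2, the share ratio was 0.974 for monocytes (reversed), 0.560 for macrophages and 1.11 for neutrophils. Log2 ratios there reversed to -0.55 for Itgax in monocytes and -0.18 for Csmd3 in neutrophils. With 15 principal components, the share ratio was 0.908 for monocytes (reversed), 0.536 for macrophages, 1.93 for microglia and 1.15 for neutrophils. With proliferation genes left out of clustering, the share ratio was 1.16 for monocytes. With the stricter cell filter, the share ratio was 0.882 for monocytes (reversed) and 1.23 for neutrophils. Log2 ratios there reversed to -0.65 for Itgax in monocytes and -0.033 for Csmd3 in neutrophils. When the libraries were clustered separately, the share ratio was 0.700 for macrophages, 1.39 for microglia and 1.11 for NK cells (reversed). Log2 ratios there reversed to -1.77 for Itgax in monocytes, -0.12 for Thbs1 in macrophages, 0.20 for Retnlg in macrophages, -0.61 for Il1b in macrophages, 0.99 for S100a9 in microglia and -0.0737 for Il1b in neutrophils. List medians there were for type I interferon -0.61 in conventional DCs, -2.12 in monocytes, -0.59 in macrophages, -1.05 in microglia, -1.07 in neutrophils, -0.59 in T cells and 0.43 in NK cells. Medians were for MHC class II 0.10 in conventional DCs, -0.85 in microglia, -1.85 in neutrophils, -0.82 in NK cells, -0.85 in monocytes and -0.13 in macrophages. For the homing list they were 0.35 in conventional DCs. Medians for interferon-gamma were -2.76 in monocytes, -0.51 in macrophages, -1.33 in microglia, -1.43 in neutrophils and 0.0592 in T cells. In the proliferation list they were 0.26 in macrophages (reversed), -0.67 in microglia, 2.85 in NK cells, 0.24 in conventional DCs and 4.32 in monocytes. Medians were for damage-associated -0.44 in microglia. For the complement list they were 0.24 in neutrophils (reversed). Medians for STAT4-linked were 0.057 in T cells. In the dissociation stress list they were 0.17 in monocytes, -0.0818 in macrophages (reversed), 0.29 in microglia, 0.0751 in neutrophils (reversed), 0.11 in T cells and -0.39 in NK cells. With no doublets removed, the share ratio was 0.677 for macrophages. Log2 ratios there reversed to 0.0701 for S100a9 in microglia. List medians there were for type I interferon -0.59 in conventional DCs, -0.86 in neutrophils, -0.57 in T cells and -0.51 in NK cells. Medians were for MHC class II 0.042 in conventional DCs, -0.32 in NK cells, -0.27 in monocytes, -0.088 in macrophages and -0.23 in T cells. For the interferon-gamma list they were -0.63 in macrophages, -1.10 in neutrophils, -0.25 in T cells and -0.47 in NK cells. Medians for free RNA were -1.22 in macrophages and 0.81 in T cells. In the proliferation list they were -0.91 in microglia and 0.25 in conventional DCs. Medians were for complement -0.28 in neutrophils and -0.24 in T cells (reversed). For the STAT4-linked list they were 0.10 in NK cells. Medians for dissociation stress were 0.63 in conventional DCs, 0.21 in monocytes, 0.0905 in macrophages and -0.19 in neutrophils. The Stat4 log2 ratio was -0.48 in microglia and -0.0136 in T cells. With the looser cell filter, the share ratio was 1.11 for neutrophils. With thinned cells, log2 ratios reversed to -0.0379 for Tnf in T cells. With per-cell means of CPM, log2 ratios reversed to -0.0348 for Tnf in T cells. With random lists not matched on expression, the list percentile was 95.9 for MHC class II in conventional DCs and 5.28 for dissociation stress in neutrophils. With median-of-ratios scaling, list medians were for interferon-gamma -0.48 in macrophages, -1.72 in microglia and -1.04 in neutrophils. In the type I interferon list they were -0.32 in macrophages, -1.48 in microglia and -0.78 in neutrophils. Medians were for MHC class II -1.06 in microglia, -0.93 in neutrophils and 0.10 in macrophages. For the damage-associated list they were -0.92 in microglia. Medians for proliferation were -1.17 in microglia. In the complement list they were -0.48 in neutrophils. Medians were for dissociation stress 0.25 in macrophages, -0.13 in microglia and -0.22 in neutrophils. With list members of 20 or more UMIs, list medians were for free RNA -1.46 in macrophages. For the STAT4-linked list they were -0.13 in T cells. Medians for MHC class II were -0.86 in NK cells. With members of 200 or more UMIs, list medians were for interferon-gamma -1.55 in microglia. In the free RNA list they were 2.53 in microglia. Medians were for STAT4-linked -0.13 in T cells and 0.11 in NK cells. For the MHC class II list they were -2.30 in NK cells and -0.28 in monocytes. Thinned to 1000 UMIs, the Il23r share ratio in T cells was 2.35. With cycling set at 5 or more genes, the cycling ratio was 0.302 in conventional DCs and 0.890 in macrophages. Set at 2 or more genes, the cycling ratio was 0.431 in microglia. Without thinning, the cycling ratio was 0.428 in microglia.

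With microglia left out of the total, the share ratio was 1.05 for conventional DCs (reversed), 1.26 for plasmacytoid DCs, 1.75 for monocytes, 0.821 for macrophages, 0.643 for T cells, 1.04 for NK cells (reversed), 0.630 for B cells and 1.92 for neutrophils. With doublets removed at the automatic threshold, the share ratio was 0.669 for plasmacytoid DCs, 1.17 for monocytes, 0.456 for macrophages and 2.04 for microglia. Log2 ratios there reversed to -0.91 for Cox6a2 in conventional DCs, -0.0918 for Apoe in conventional DCs, -0.00184 for Dusp1 in monocytes, -1.42 for Hba-a2 in microglia, -4.49 for Hbb-bs in microglia, -5.79 for Hba-a1 in microglia, 0.77 for S100a9 in microglia, -0.64 for S100a9 in T cells, -1.37 for Cst3 in T cells, -1.93 for Tanc2 in NK cells and -0.73 for Csmd3 in neutrophils. List medians there were for type I interferon -0.35 in conventional DCs, -0.43 in monocytes, -0.70 in neutrophils, -0.86 in T cells and -0.80 in NK cells. Medians for interferon-gamma were -0.84 in monocytes, -0.60 in macrophages, -0.90 in neutrophils, -0.25 in T cells and -0.70 in NK cells. In the proliferation list they were -1.53 in macrophages, 1.14 in NK cells, 0.00693 in monocytes and 0.27 in T cells. Medians were for MHC class II -3.39 in neutrophils, -2.00 in NK cells, -0.11 in monocytes, 0.15 in macrophages and -1.74 in T cells. For the complement list they were -2.11 in neutrophils and -2.99 in T cells (reversed). Medians for STAT4-linked were 0.15 in T cells. In the free RNA list they were -4.50 in T cells (reversed). Medians were for dissociation stress -0.11 in monocytes (reversed), -0.19 in macrophages (reversed), -0.077 in microglia, -0.69 in neutrophils and -0.24 in T cells (reversed). The cycling ratio was 0.261 in macrophages. The Stat4 log2 ratio was -0.49 in all cells, 0.30 in conventional DCs, -1.37 in macrophages, 0.19 in T cells (reversed) and 0.0114 in NK cells. Without the subclusters led by T cell, microglia and plasmacytoid DC genes, log2 ratios reversed to -0.28 for Cox6a2 in conventional DCs. List medians there were for interferon-gamma -0.29 in conventional DCs. For the type I interferon list they were -0.29 in conventional DCs. Medians for dissociation stress were 0.40 in conventional DCs. The Stat4 log2 ratio was 0.27 in conventional DCs. With thinned cells, list medians were for interferon-gamma -0.53 in conventional DCs, -0.90 in monocytes, -0.50 in macrophages, -1.73 in microglia and -0.57 in neutrophils. In the type I interferon list they were -0.26 in macrophages, -1.70 in microglia and -0.70 in neutrophils. Medians were for proliferation -0.39 in macrophages, -1.24 in microglia and 0.68 in NK cells. For the MHC class II list they were -1.05 in microglia, -1.58 in neutrophils, -0.24 in monocytes and -0.18 in T cells. Medians for damage-associated were -0.94 in microglia. In the free RNA list they were 1.85 in microglia and 0.36 in T cells. Medians were for complement -0.89 in neutrophils. For the STAT4-linked list they were -0.20 in T cells. Medians for dissociation stress were -0.0692 in microglia, -0.28 in neutrophils, 0.000629 in T cells and -0.35 in NK cells. Without the subclusters led by T cell and microglia genes only, list medians were for type I interferon -0.32 in conventional DCs. In the MHC class II list they were 0.11 in conventional DCs. Medians were for dissociation stress 0.38 in conventional DCs.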

Other observations

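The tests of scaling and of free RNA in the first pattern were chosen only after its values were seen; the other tests were written before their own values but after the patterns had been noticed. All 3 patterns are hypotheses, found and tested on the same libraries.

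Interferon-gamma response genes such as Iigp1 and Cxcl9 were lower in conventional DC-like, monocyte-like, inflammatory macrophage-like, microglia-like and neutrophil-like cells of Stat4fl/flCD11cCre. Class make-up differed too. The Cxcl10-led cluster went from 42.3% to 21.7% of monocyte-like cells, and the Ccl12-led cluster from 55.7% to 12.9% of microglia-like cells. In neutrophil-like cells the Retnlg-led cluster went from 27.7% to 49.0%. How much of the list medians such shifts carry was not tested. The highest list median over the 5 classes with median-of-ratios scaling and thinned cells was -0.462. It lay below a limit of -0.25, which was set after the values were seen. Scaling shifts each list by the class median of all genes, -0.195 to 0.0977 here. It could not have reached that limit, so the scaling part of the test decides nothing. In conventional DC-like cells the list median lay closer to the limit without some subclusters, as given above. Free RNA would have reached T cell-like cells too. There the median over list members of the loss, as a part of the loss in the class, was at most 0.0264 over the 5 classes. Thinned cells moved the neutrophil median from -1.24 to -0.569 (-0.750 to -0.485) and the monocyte median from -1.19 to -0.904 (-1.04 to -0.704), so their size depends on the setting. With all their UMIs, the cells deep enough to thin had -1.002 in neutrophils and -1.20 in monocytes, and with only the members still measured after thinning -0.984 and -0.988. Shallow cells thus moved the neutrophil value but not the monocyte value, members lost moved the latter, and thinning itself moved the neutrophil value most. A candidate explanation is less interferon-gamma near these cells, since T cell-like cells took 8.24% against 17.2% of cells. Ifng was lower in their Cd40lg-led cluster (510 to 312 CPM, log2 -0.71), in the Foxp3-led cluster (log2 -2.02) and in NK cell-like cells. Ifng was higher in the proliferating T cell cluster (log2 0.90), and in the Cd8b1-led cluster its interval spans 0 (log2 -0.29, -0.72 to 0.13). The fall was thus not shared by all T cell clusters. No test of this explanation was made. The sort for MHC class II and CD11c should remove most T cells and so need not keep their share. The type I interferon list was lower too in the 5 classes (-0.40 to -1.38) and in T cell-like cells (-0.40). A difference between the 2 pools other than the Stat4 genotype, such as disease severity, cannot be told apart from it with 1 library per genotype.

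Itgad, 4931431B13Rik and Cox6a2, which follow Itgax on chromosome 7, were higher in several classes of Stat4fl/flCD11cCre; their mean of 2.20 over class medians ranked 1 of 10450 runs of 3 neighbouring genes, a ranking chosen after these genes, and the surroundings of Itgax, Plcb4 and Stat4, had been looked at. CD11c-Cre transgenes can carry a stretch of genome around Itgax, and extra copies of such neighbours may be the source: Itgad and 4931431B13Rik together went from 63 to 179 UMIs in the cells outside the 7 compared classes (log2 1.48, 1.06 to 1.92), which the idea needed. Itgad (log2 -1.31) and Cox6a2 (log2 -1.15) were lower in microglia-like cells, but Itgax fell there too (log2 -1.235). Those falls therefore do not decide on extra copies. Against a simple copy effect, Cox6a2 was also lower in inflammatory macrophage-like cells (log2 -1.16), where Itgax was at -0.03. Itgad overlaps the other genes on the opposite strand, so their reads are uncertain where strand was not used. Plasmacytoid DC RNA stays open as the source of Cox6a2 in NK cell-like cells: the other plasmacytoid DC markers rose by a log2 of 0.781 (0.512 to 1.05), which includes the 1 that was set as the limit.

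Those markers did not move alike in NK cell-like cells. Siglech went from 5.26 to 23.5 CPM, Ly6d from 0.405 to 14.2, Tcf4 from 51.0 to 71.0 and Pacsin1 from 16.6 to 10.2, while Cox6a2 went from 10.9 to 112. A later calculation, made after these values were seen and deciding nothing, put the gain of the markers at 21.0% (up to 31.2%) of what the plasmacytoid DC RNA needed for Cox6a2 would bring.

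Il17a, the Th17 cytokine, was higher in T cell-like cells of Stat4fl/flCD11cCre. Gamma-delta T cells among them did not account for it, since without cells that hold a gamma-delta UMI the log2 ratio was 2.12 (2.02 to 2.22). The share of thinned T cell-like cells with an Il17a UMI went from 3.50% to 6.88% (ratio 1.97, 1.37 to 2.83, unthinned 4.21% and 9.31%). In thinned microglia-like cells it was 0.113% and 0.0651%. The T cell ratio passed the limit set beforehand, but the CPM of Il17a rose by more than the share. A small set of cells with many Il17a UMIs may therefore still carry most of the rise. Free RNA did not account for it, as the gain pooled over other cells was 0.0912% of the gain in T cell-like cells. Il17a was also higher in NK cell-like (log2 3.46) and inflammatory macrophage-like cells (log2 1.61). The rise may be a shift toward Th17 cells in the Stat4fl/flCD11cCre pool, or a difference between the pools. It lay mainly in the Cd40lg-led cluster (151 to 766 CPM, 925 and 2699 UMIs). Il17a was also higher in the Foxp3-led cluster (2.41 to 126 CPM), but on only 5 and 172 UMIs. How many cells of that cluster held them was not examined. The direction reversed in the proliferating cluster (105 to 38.5 CPM).

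Some genes moved the same way in all 7 compared classes. Hspa1a and Hspa1b, heat-shock genes that also respond to tissue handling, were lower in each, with medians over classes of -1.25 and -1.30. The dissociation stress list they belong to did not move alike, with a median of 0.50 in conventional DC-like, 0.30 in monocyte-like and -0.41 in neutrophil-like cells. Plcb4, which encodes a phospholipase, and Wdfy1, an endosomal protein gene, were higher in each, with medians over classes of 2.83 and 1.31.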
